A study of Synechocystis sp. PCC 6803 with 8 samples.

How the data were processed

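The arrays are 1-colour Agilent arrays of a custom design (075764 in the file headers) on which RNA was labelled directly, per the labels' protocols. Images were read with Agilent Feature Extraction 10.7.3.1, per the file headers, and the deposited spot files give each spot's intensity on a linear scale, including a processed signal after background subtraction, a median signal and a median local background. All 8 arrays were on 1 slide and had 1 scan date, per the file headers, so neither was a batch. The deposited table of the whole series holds log2 values for the same spots. Per the submitters' processing notes limma was used by the authors; its settings are not given in the sources used here. Within each array the rank correlation of that table with the spot file's median signal was 1, and with the processed signal 0.984 to 0.996, so it follows the signal before local background subtraction. Its array medians were 10.07, 10.21, 10.29 and 10.43 for the mutant and 10.39, 10.28, 10.12 and 10.21 for WT, in the order with N replicates 1 and 2 and no N replicates 1 and 2. Its values are log2 on the scale of the scanner signal and have a common direction, while the method that normalized them stays unknown.

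The main values were computed as log2 of the processed signal minus the array's 75th percentile over the 61015 probes that are not control spots. Each file holds 62334 spots, of which 1319 are controls, and every probe has 1 spot. Control spots were left out, as were 17 probes flagged as outliers on any array. A probe was tested where it was well above background on both arrays of at least 1 group, which kept 41714 probes and left out 19284. Of the tested probes, 27371 were well above background on all 8 arrays. No spot was saturated. Where a probe was well above background on neither array of a group, a fold is given as "at least": the mean of the brighter group against the mean over the dimmer group's arrays of the higher of the lowest signal among probes well above background and the probe's own signal, all on the normalized log2 scale. An adjusted p beside such a fold is that of the fitted change, which uses the probe's signals near background as they are. It does not test the "at least" fold.

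The design was a mean for each of the 4 groups, fitted to all 8 arrays with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with 5 contrasts: nitrogen removal in each strain, mutant minus WT in each medium, and the difference of the nitrogen responses. P-values were adjusted by Benjamini-Hochberg within a contrast, with a threshold of 0.05 and no minimum fold. The prior degrees of freedom were 2.69, and 10.2 with only probes well above background on all 8 arrays. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted over 4 lists in each contrast. LEADER2, with 2 tested probes, was not tested as a list, and its median change without nitrogen was -0.29 in WT and -0.37 in the mutant. Relations along the probe number were tested with 100000 permutations, two-sided, in a family of 9, and 1e-05 is the smallest p these can give. The 3 on level are given only as a limit, without p, because the signals of different probes cannot be compared. The fit was tested on simulated data with the probes' own residual spreads, where a change of 2 (log2) between mutant and WT with N was recovered for 64% of 50 changed probes among 41714, and one of 1 for 16%. Only 87 probes passed in that simulation, against 4781 in the data. Since the adjusted threshold depends on how many probes change, these shares are not the power of the real test.

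The groups, comparisons, tests and most processing alternatives were set before the data were examined. So were gene lists with 330 members and a rule for named genes: the most changed genes and non-coding features in each contrast, list members, and nitrogen-responsive transcripts of the textbooks. The files name no genes. Of the 61015 probe names, 0 equal a locus tag, symbol or synonym among the 3347 genes of the reference table, so the fixed lists, the textbook transcripts and sniP3 are not analysed here, and the probe is the unit of every test. The files do not pair the serial numbers with gene names, so at most 2 numbered probes that rose and 2 that fell are named in each comparison, those with the largest change among probes that passed, were well above background on all arrays compared and, in comparisons of 2 groups, did not overlap. The lists CRISPR1, CRISPR2, CRISPR3, LEADER1 and LEADER2 were formed from the probe names after the files had been seen. Named members are among the 2 most changed ones past the test in each direction and comparison. CRISPR2-1, CRISPR3-1, LEADER1-4 and CRISPR1-24 were chosen as points of comparison after their values were seen.

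Alternatives, of which normexp on the median signal (offset 50), the scaled deposited table, a common floor and crossed replicate numbers were chosen after seeing the data, covered the scaling, background correction, source of values, filter on dim probes, variance model, arrays in the fit, replicate number as a block, thresholds and leaving out each array. Correlations of replicate arrays over tested probes were 0.956 in WT with N, 0.984 in WT no N, 0.981 in mutant with N and 0.986 in mutant no N, and no arrays were duplicates.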

Results

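Total RNA of the cyanobacterium Synechocystis was hybridised to 8 microarrays, each with a sample of its own, to ask how the transcripts respond to loss of nitrogen and to loss of the small protein SniP3. The samples formed 4 groups of 2: wild type (WT) and a mutant lacking sniP3, each grown with a nitrogen source and each grown for 48 h in medium without one, at a light intensity of 100 µmol photons. One label places the samples with nitrogen under standard growth conditions, which the protocol defines by a lower light, whereas the treatment text gives the higher light and 48 h for both media; the latter is used here. Each array carried 61015 probes for the organism. Of these, 60866 had only a serial number as their name, 142 were named for the CRISPR arrays of the organism and 7 for the leaders of such arrays. A CRISPR array is a row of repeats and spacers whose transcript is processed into the guide RNAs of a bacterial immune system, and its leader is the stretch before the first repeat. The share of probes well above background ranged from 47.9% on WT with N replicate 2 to 79.6% on WT with N replicate 1, and the 75th percentile of the processed signal ranged from 764 to 1454. With 2 arrays per group the number of arrays limits the precision, and nothing in the labels says whether the replicates came from separate cultures, so adjusted p-values measure the spread between these samples, which may be technical. No probe was paired with sniP3 in the sources used here, so the deletion could not be checked on the arrays.

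In WT the probes of CRISPR2 and CRISPR3 were lower without nitrogen. All 42 tested CRISPR2 probes were lower without nitrogen, with a median log2 change of -2.12, which is 4.36-fold. Of the 30 tested CRISPR3 probes, 28 were lower and 2 did not pass the test, with a median of -1.61. Adjusted over the list alone, 42 CRISPR2 and 30 CRISPR3 probes were lower. The CRISPR1 probes had a median of -0.09, with 1 of 47 higher, 1 lower and 45 not past the test. CRISPR2-1, measured on all 8 arrays, went from 5.05 ± 0.45 to 3.38 ± 0.27 (log2, mean ± SD, n = 2), a change of -1.67 with a standard error of 0.25 and an adjusted p of 0.00569. CRISPR2-45 and CRISPR2-55, not well above background in WT without nitrogen, were at least 2.62-fold (adjusted p = 0.00159) and at least 3.23-fold lower (adjusted p = 0.0241). CRISPR3-12 and CRISPR3-21 were at least 3.07-fold and at least 3.8-fold lower (adjusted p = 0.00133 for both). Of the 4 LEADER1 probes 3 rose, among them LEADER1-2 by 1.25 (adjusted p = 0.0101) and LEADER1-3 by 0.91 (adjusted p = 0.0200), while LEADER1-4 stood at -0.09 (adjusted p = 0.673). With only the 4 WT arrays in the fit, the calls of LEADER1-2 and LEADER1-3 were lost (limma adjusted p = 0.0577 and 0.0869). Without WT no N replicate 1 the calls of CRISPR2-1 (adjusted p = 0.0512), CRISPR2-55 (0.139), LEADER1-2 (0.058) and LEADER1-3 (0.101) were lost, and without WT no N replicate 2 those of LEADER1-2 (adjusted p = 0.0622) and LEADER1-3 (0.0946).

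**Figure D1:**
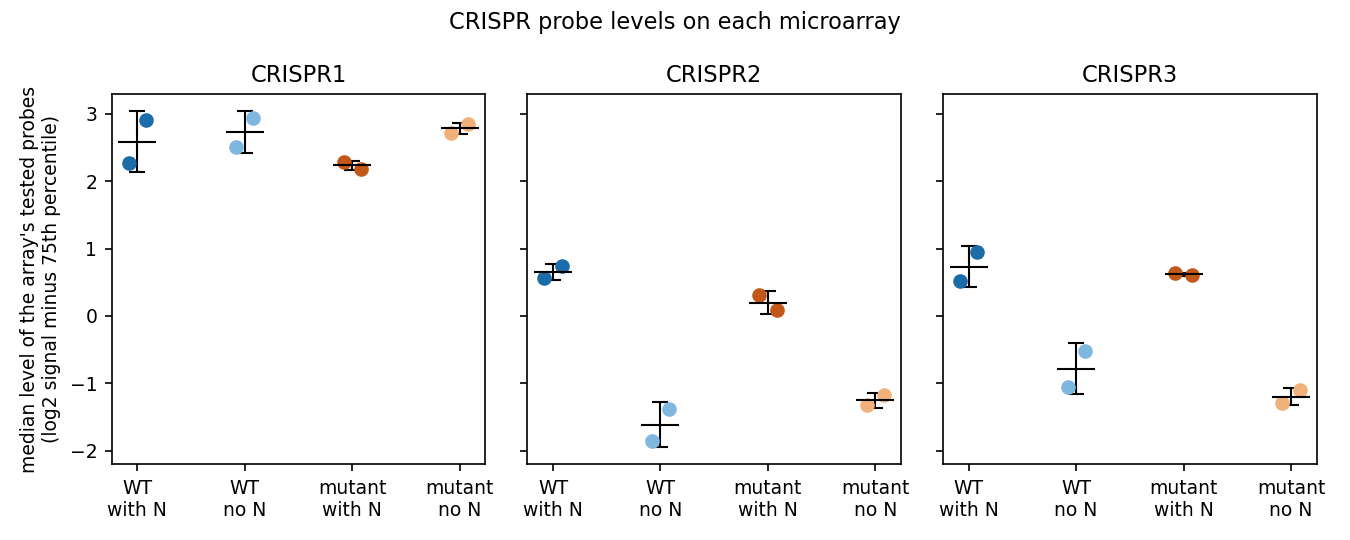
Median level of the tested probes of CRISPR1, CRISPR2 and CRISPR3 on each array, as log2 signal minus the array's 75th percentile. Points are arrays (n = 2 per group), bars are the group mean and error bars the SD. CRISPR2 went from 0.65 to -1.62 in WT and from 0.20 to -1.25 in the mutant when nitrogen was absent, while CRISPR1 stayed between 2.23 and 2.78 in the group means.

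Compared with all other tested probes by camera, with a preset correlation between probes, the adjusted p in WT was 3.5e-21 for CRISPR2, 8.49e-15 for CRISPR3, 0.841 for CRISPR1 and 0.0563 for LEADER1. LEADER1, with a median of 0.82, passed in 14 of 27 alternatives, with an adjusted p of 0.0311 after quantile normalization, 0.0071 without WT with N replicate 2 and 0.0356 without WT no N replicate 1, and did not pass in 13, with 0.312 at an estimated correlation. With an estimated correlation no list passed, with an adjusted p of 0.971 for CRISPR1 and 0.119 for CRISPR2 and for CRISPR3, where the estimated correlation between probes was 0.441 and 0.328. By fry, which asks only whether the members of a list move one way, the adjusted p was 0.000432 for both, 0.0173 for LEADER1 and 0.82 for CRISPR1. The median over members measured on both sides was -1.98 for CRISPR2 (30 probes) and -1.58 for CRISPR3 (23 probes). The sign of the CRISPR1 median was not settled, since it was 0.13 after quantile normalization, 0.15 after cyclic loess and 0.17 without scaling. Without WT with N replicate 1 it was -0.39 (camera adjusted p = 0.00126), against 0.26 without WT with N replicate 2 (camera adjusted p = 0.00248) and 0.11 without WT no N replicate 1, and it was -0.28 without WT no N replicate 2.

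Over all probes, 14219 of 41714 tested probes differed between the media in WT, 6187 higher and 8032 lower without nitrogen. Of these, 3312 higher and 3736 lower ones had a fitted change of at least 2-fold, which is no measured size for probes near background, and 10911 were well above background on all 4 arrays. Both arrays of one group lay above both of the other for 69.4% of the probes, where a random order of the arrays gives 33.3% for a single probe. All probes share the same arrays and their offsets, so 33.3% is no baseline for the set. The lowest normalized signals were -4.44 and -4.60 on the mutant with N arrays and -5.16 and -4.92 on the mutant no N arrays. A probe at that floor on all of these arrays is thus counted as not overlapping. That share was 73.5% for nitrogen removal in the mutant, 54.2% for mutant minus WT with N and 65.6% without N. The last 2 compare the strains, so such a share does not single out a response to nitrogen. Among probes measured on both sides, SYN-CR-76-31477 rose the most, from -0.82 ± 0.32 to 3.35 ± 0.36 (18-fold, adjusted p = 0.00208), followed by SYN-CR-76-44542 (17.2-fold, adjusted p = 0.00266). SYN-CR-76-29604 fell from 1.86 ± 0.02 to -2.17 ± 0.02 (16.3-fold, adjusted p = 0.00107) and SYN-CR-76-40997 fell 15.0-fold (adjusted p = 0.00162). Without WT no N replicate 1, 2970 probes passed, and without WT no N replicate 2, 5493 passed. Higher calls were 43.5% of all calls here, 55.2% after quantile normalization, and between 28.4% with no filter (5355 higher, 13496 lower) and 64% without scaling over all alternatives, with 34.6% in the authors' deposited values.

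In the mutant, the CRISPR2 and CRISPR3 probes were also lower without nitrogen. Of 42 CRISPR2 probes, 39 were lower and 3 did not pass, with a median of -1.47. Of 30 CRISPR3 probes, 24 were lower and 6 did not pass, with a median of -1.94. Adjusted over the list alone, 39 CRISPR2 and 25 CRISPR3 probes were lower. CRISPR3-15 was at least 5.2-fold lower (adjusted p = 0.000395), CRISPR3-27 at least 3.79-fold lower (adjusted p = 0.000395) and CRISPR2-10 at least 5.5-fold lower (adjusted p = 0.00115). LEADER1-3 rose by 1.11 (adjusted p = 0.0111) and LEADER1-1 by 0.90 (adjusted p = 0.0172), and 3 of the 4 LEADER1 probes rose in all. CRISPR1 had a median of 0.51, with 46 of 47 values above 0, but only 1 probe passed by itself. That probe, CRISPR1-8, was well above background on 0 of the 2 mutant arrays with nitrogen and on 1 of the 2 without it, and its call was lost without mutant no N replicate 1 (adjusted p = 0.0522). Leaving out any 1 mutant array ended the calls of LEADER1-1 and LEADER1-3, with adjusted p between 0.0549 and 0.115.

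In the camera test the mutant gave an adjusted p of 2.18e-17 for CRISPR2, 2.33e-15 for CRISPR3, 2.52e-06 for CRISPR1 and 0.0307 for LEADER1. With an estimated correlation the adjusted p was 0.157 for CRISPR2 and for CRISPR3, 0.415 for CRISPR1 and 0.281 for LEADER1. By fry it was 0.00156, 0.00053, 0.115 and 0.0138 in the same order of lists. Without mutant with N replicate 2 the camera adjusted p of LEADER1 was 0.0626. In the whole set, 12022 of 41714 probes changed in the mutant, 5677 higher and 6345 lower. With only the 4 arrays of each comparison, 15729 probes passed in the mutant and 4634 in WT, and with array weights 17696 and 7198. Which strain gave more calls therefore depends on how the spread is estimated. SYN-CR-76-34316 rose from -1.06 ± 0.83 to 3.98 ± 0.11 (32.8-fold, adjusted p = 0.000981) and SYN-CR-76-29324 rose 31.2-fold (adjusted p = 0.00043). SYN-CR-76-26029 fell from 4.62 ± 0.19 to -0.03 ± 0.03 (25.1-fold, adjusted p = 0.000395) and SYN-CR-76-830 fell 24.8-fold (adjusted p = 0.000812). Without mutant with N replicates 1 or 2, 5800 or 6133 probes passed, without mutant no N replicates 1 or 2, 4480 or 3729, and without either WT with N array, 18394. Higher calls were 47.2% of all calls here, 37.7% with only probes well above background on all 8 arrays, 60.3% with the 75th percentile taken over probes detected on all arrays, 91.3% without scaling and 85.5% in the authors' deposited values.

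**Figure D2:**
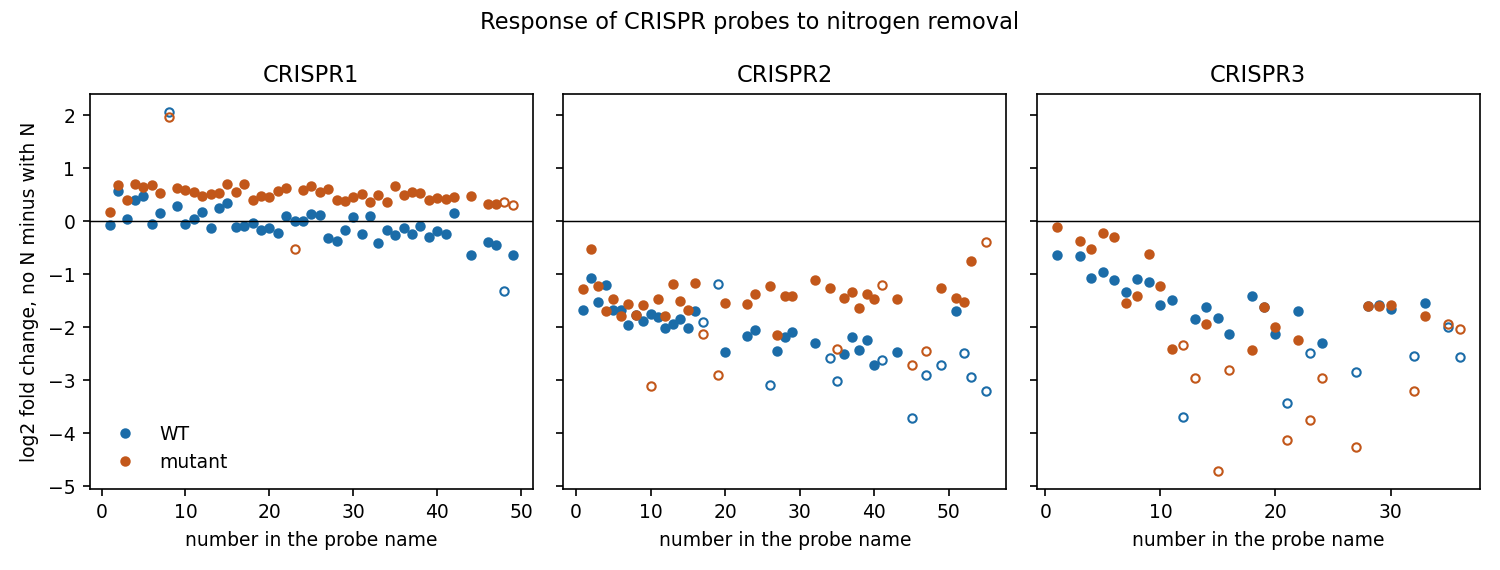
Log2 fold change without nitrogen of each tested CRISPR probe against the number in its name, in WT (blue) and mutant (orange). Filled points were well above background on all 4 arrays of that strain, open points were not and have a fold change that is no measured size. CRISPR3-1 lies at -0.63 in WT and -0.11 in the mutant, above the list medians of -1.61 and -1.94, and its value in the mutant was 0.76 after quantile normalization and 0.68 after cyclic loess.

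For CRISPR probes measured on both sides, which are not independent replicates, the change without nitrogen in WT became more negative with the number in the probe name, with rho of -0.800 in CRISPR2 (r = -0.716, 30 probes, adjusted p = 3e-05 by permutation, where 1e-05 is the smallest unadjusted p these can give), -0.729 in CRISPR3 (r = -0.660, 23 probes, adjusted p = 0.00013 by permutation) and -0.681 in CRISPR1 (r = -0.699, 45 probes, adjusted p = 4.5e-05 by permutation). In the mutant rho was -0.726 for CRISPR3 (19 probes, adjusted p = 0.00085 by permutation) and -0.452 for CRISPR1 (43 probes, adjusted p = 0.003 by permutation), and 0.186 for CRISPR2 (34 probes, adjusted p = 0.29 by permutation). Leaving out the 2 probes farthest from the median number kept r between -0.526 and -0.847 in these relations, except for CRISPR2 in the mutant, where r was 0.0147. The level in WT with nitrogen also fell with the number, with rho of -0.498 in CRISPR1, -0.74 in CRISPR2 and -0.723 in CRISPR3 over all tested probes. A relation with the number therefore cannot be told apart from one with the signal level.

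The nitrogen responses of both strains were correlated across the 41714 probes, with r = 0.637 and rho = 0.592, and r between 0.41 and 0.735 over 16 choices of 1 array per group. The comparisons share no array. Of the probes called in both, 3225 were higher in each, where independent lists give 842, 3368 were lower in each, where independent lists give 1222, and 168 went opposite ways. Of the 14219 probes called in WT, 87.1% had the same sign in the mutant.

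**Figure D3:**
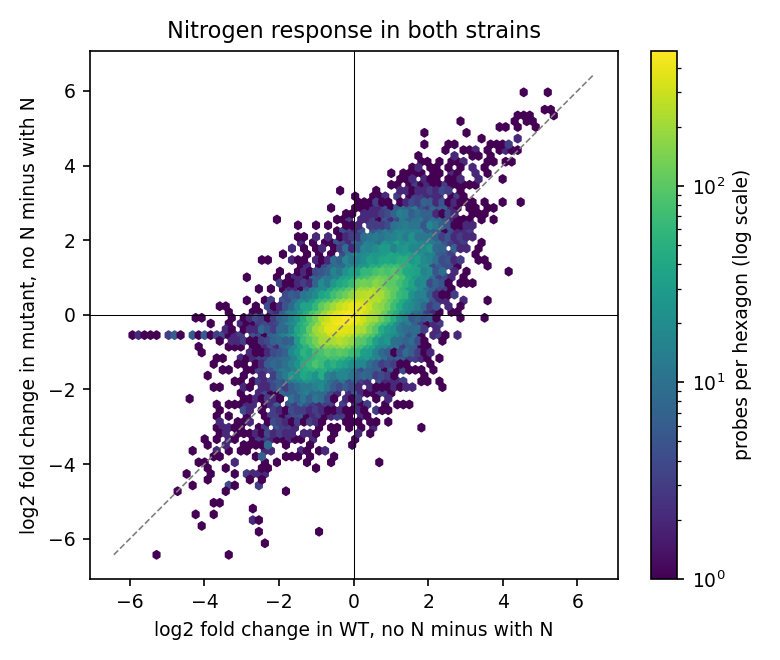
Log2 fold change without nitrogen in the mutant (vertical) against WT (horizontal) for 41714 probes, as probes per hexagon on a log colour scale, with a dashed line of equality. Most of the cloud follows the line (r = 0.637), and a horizontal streak in the mutant, where CRISPR1-23 lies with -0.52, is made of probes at the lowest processed signal of each mutant array.

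Between the strains with nitrogen, 1 CRISPR probe stood out. CRISPR1-23 was at 0.58 ± 0.43 in WT and at -4.52 ± 0.12 in the mutant, where it was well above background on neither array, and it was at least 6.85-fold lower (adjusted p = 0.000158). The remaining 46 tested CRISPR1 probes had a median of -0.48. Of all 47, 3 were lower and 44 did not pass, and adjusted over the list alone 1 CRISPR1, 2 CRISPR2, 5 CRISPR3 and 2 LEADER1 probes were lower. CRISPR1-48 was at least 1.96-fold lower (adjusted p = 0.0483), a call lost without any 1 of the 8 arrays. CRISPR3-6 was lower by a log2 difference of -1.29 (adjusted p = 0.00636, and 0.0558 without mutant with N replicate 2) and CRISPR2-26 by -1.05 (adjusted p = 0.0314, and 0.0708 to 0.169 without any 1 mutant array), with 4 of 30 CRISPR3 and 2 of 42 CRISPR2 probes lower in all. With only the 4 arrays compared, the calls of CRISPR1-48 (limma adjusted p = 0.121), CRISPR3-6 (0.0944) and CRISPR2-26 (0.122) were lost. That of CRISPR1-23 held. In the camera test the adjusted p was 3.13e-06 for CRISPR1, 0.0061 for CRISPR2 and 0.0207 for CRISPR3. With an estimated correlation it was 0.466 for each of them, and by fry it was 0.106, 0.134 and 0.106. The medians of -0.48, -0.27 and -0.19 of CRISPR1, CRISPR2 and CRISPR3 were -0.20, -0.18 and -0.19 without WT with N replicate 2 (camera adjusted p = 0.549, 0.719 and 0.549), and -0.77, -0.45 and -0.33 without WT with N replicate 1. Without mutant with N replicate 2 the median was -0.16 for CRISPR2 (camera adjusted p = 0.0978) and -0.22 for CRISPR3 (0.0667), and without mutant with N replicate 1 it was -0.40 for CRISPR2.

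In this comparison 4781 of 41714 probes differed, 2053 higher and 2728 lower in the mutant. SYN-CR-76-16088 was higher, at 4.61 ± 0.06 against -0.17 ± 0.23 (27.6-fold, adjusted p = 4.33e-05), as was SYN-CR-76-9811 (22.4-fold, adjusted p = 6.14e-05). SYN-CR-76-3466 was lower, at -1.10 ± 0.30 against 5.48 ± 0.23 (95.1-fold, adjusted p = 3.51e-05), as was SYN-CR-76-54317 (71.9-fold, adjusted p = 1.79e-05). The WT arrays with nitrogen differed from each other by a median of 0.356 (log2), against 0.151 to 0.204 in the other groups. Without WT with N replicate 2, 12027 probes passed, 3949 higher and 8078 lower, and without mutant with N replicates 1 or 2, 1777 or 870 passed. Without either mutant no N array 2105 passed, and without either WT no N array 2157. Higher calls were 42.9% of all calls here, 63.5% after quantile normalization, 23.3% with the 75th percentile over probes detected on all arrays, 2.84% without scaling and 22.1% in the authors' deposited values. They were 57.8% of the calls when only probes well above background on all 8 arrays were tested, 58.2% without WT with N replicate 1, 28.4% with no filter and 6.41% with only the 4 arrays of the comparison.

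**Figure D4:**
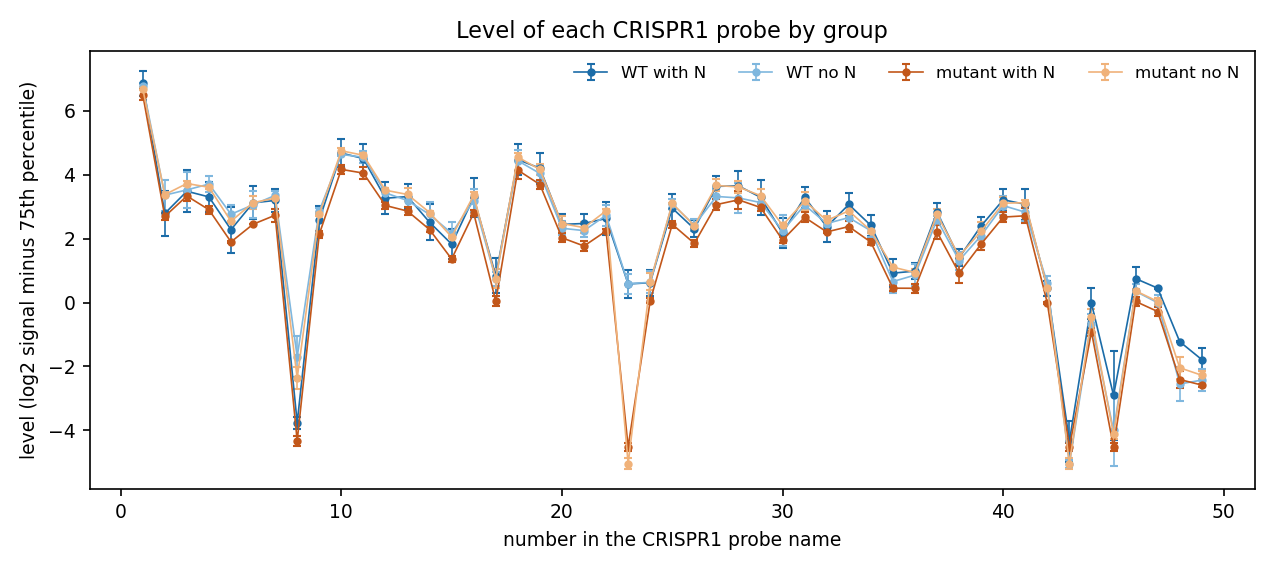
Level of each CRISPR1 probe (log2 signal minus the array's 75th percentile) against the number in its name. Points are group means and error bars the SD over 2 arrays. CRISPR1-23 lies at 0.58 and 0.59 in WT and at -4.52 and -5.04 in the mutant, while CRISPR1-24 differed between the strains by -0.56 with nitrogen (adjusted p = 0.203) and 0.02 without it (adjusted p = 0.98).

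Between the strains without nitrogen, CRISPR1-23 was again lower in the mutant, at -5.04 ± 0.17 against 0.59 ± 0.31 in WT, at least 9.87-fold (adjusted p = 0.000174). It was the only one of 47 CRISPR1 probes past the test, and the 46 others had a median of 0.095. The median of all 47 was 0.09 (camera adjusted p = 0.184), but 0.26 without WT no N replicate 2 (camera adjusted p = 0.000732), 0.20 without mutant no N replicate 1 (0.0412), 0.01 without mutant no N replicate 2 (0.82) and -0.10 without WT no N replicate 1 (0.183). Of the CRISPR3 probes 3 of 30 were lower. CRISPR3-15 was at least 1.24-fold lower, and its limma adjusted p of 0.00187 is that of the fitted change, not of this limit. Adjusted over the list alone 9 CRISPR3, 2 CRISPR2, 1 CRISPR1, 3 LEADER1 and 2 LEADER2 probes were lower. The call of CRISPR3-15 was lost without scaling (limma adjusted p = 0.0545) and in the authors' deposited values (-0.152, limma adjusted p = 0.429). CRISPR3 had a median of -0.53 and CRISPR2 of 0.24, with camera adjusted p of 7.07e-07 and 0.000538. With an estimated correlation the adjusted p was 0.504 for both, and by fry 0.058 for CRISPR3 and 0.462 for CRISPR2. Without WT no N replicate 1 the CRISPR2 median was 0.15 (camera adjusted p = 0.113), and without WT no N replicate 2 it was 0.40, with -0.30 for CRISPR3. In the authors' deposited values the CRISPR3 median was 0.05, where the median of all tested probes was 0.18.

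Without nitrogen 1154 of 41714 probes differed between the strains, 287 higher and 867 lower in the mutant. With only the 4 arrays of each comparison, 6111 probes passed here and 499 with N, and with array weights 7523 and 1159. Which medium gave more calls between the strains therefore depends on how the spread is estimated. SYN-CR-76-31735 was higher, at 4.45 ± 0.05 against -1.51 ± 0.13 (62.1-fold, adjusted p = 0.00138), as was SYN-CR-76-35590 (52.4-fold, adjusted p = 6.26e-05). SYN-CR-76-41430 was lower, at -1.92 ± 0.32 against 3.44 ± 0.07 (41.2-fold, adjusted p = 0.000268), and SYN-CR-76-3466 was lower here too (36.5-fold, adjusted p = 0.00015). In both media together, 608 probes were lower in the mutant, where independent lists give 57, and 80 were higher, where independent lists give 14. Here too both comparisons use the same spread of each probe, so 57 and 14 are no exact chance level. Without either mutant with N array 738 probes passed, without mutant no N replicates 1 or 2, 372 or 214, without WT no N replicates 1 or 2, 230 or 208, and without either WT with N array, 4157. Higher calls were 24.9% of all calls here, 41.4% after quantile normalization, 35% after cyclic loess, 13.7% with the 75th percentile over probes detected on all arrays and 4.76% without scaling. In the authors' deposited values they were 84.8%, with 5679 probes higher and 1016 lower, and with only probes well above background on all 8 arrays 54.1%. They were 9.61% with no filter and 2.42% without mutant no N replicate 1.

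WT arrays occupied row 1 of the slide and mutant arrays row 2, and arrays with nitrogen occupied columns 1 and 2, arrays without it columns 3 and 4. Strain and row therefore cannot be told apart, nor can nitrogen supply and the side of the slide.

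The response to nitrogen removal differed between mutant and WT for 17 of 41714 probes, 5 with a higher and 12 with a lower change in the mutant. No CRISPR or leader probe was among them, but adjusted over the list alone 8 CRISPR2 probes were higher, and 2 CRISPR2 and 2 CRISPR3 probes lower. SYN-CR-76-59195 rose in WT from -0.44 ± 0.21 to 1.54 ± 0.01, and its means in the mutant were 1.75 ± 0.18 and 0.46 ± 0.21, a difference of -3.27 (adjusted p = 0.0456). SYN-CR-76-57008 differed by -2.97 (adjusted p = 0.0383) and SYN-CR-76-4286 by 2.19 (adjusted p = 0.0466). With a replicate block limma called 0 probes (8403 at an unadjusted p under 0.05), with an adjusted p of 0.133 for each of these 3, and with a crossed replicate block 0 (10609 unadjusted), with 0.0579, 0.0579 and 0.0583. As lists, CRISPR1 and CRISPR2 had median differences of 0.58 and 0.61, with camera adjusted p of 4.52e-06 and 1.14e-05, with an estimated correlation the adjusted p was 0.812 for both, and by fry 0.386 and 0.357. CRISPR3 had a median of -0.11 (camera adjusted p = 0.155), which was -0.36 without WT no N replicate 1 (camera adjusted p = 0.00221) and 0.04 without WT no N replicate 2 (camera adjusted p = 0.777). Without WT with N replicate 2 the adjusted p was 0.123 for CRISPR1, 0.0667 for CRISPR2 and 0.0331 for CRISPR3, with medians of 0.29, 0.45 and -0.35, and without WT no N replicate 1 the CRISPR2 median was 0.33. Higher differences were 29.4% of the calls, 9.09% with the 75th percentile over probes detected on all arrays, 93.4% in the authors' deposited values, and 26.5% or 63.7% without WT with N replicate 1 or 2. The count of 17 rose to 3755 when only probes well above background on all 8 arrays were tested, and to 4166 without WT with N replicate 1 or 4867 without WT with N replicate 2. Without any 1 of the other 6 arrays limma called 0 probes, with 4780 to 9080 at an unadjusted p under 0.05. On simulated data of 41714 probes, the same fit recovered 0% of differences of 1 (log2), 26% of differences of 2 and 56% of differences of 3. Few probes were changed there and 43 passed in all, so recovery would differ if many more probes changed.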

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

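The tests on the sensitivity of the mutant arrays, on a shared plasmid, on the whole CRISPR1 array and on the missing spacer were chosen after the results were seen. The difference of the nitrogen responses passed its test for 17 probes, with a median difference of 0.582 for the CRISPR1 list and 0.61 for the CRISPR2 list, and both list calls were lost without WT with N replicate 2 (medians 0.293 and 0.445, camera adjusted p = 0.123 and 0.0667), and with an estimated correlation the adjusted p was 0.812 for each. Among the control spots, which no comparison uses, 46% of 350 E1A spots were well above background on mutant no N replicate 2 and 42.3% on replicate 1, against 39.7% and 29.7% on the mutant with N arrays, 32.9% and 30.6% on the WT with N arrays and 25.1% and 28% on the WT no N arrays.

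The CRISPR2 and CRISPR3 probes were lower without nitrogen in both strains, while the CRISPR1 median was 0.511 in the mutant and had no settled sign in WT (-0.086, and -0.387 without WT with N replicate 1). With an estimated correlation the camera adjusted p of CRISPR2 and of CRISPR3 was 0.119 in WT and 0.157 in the mutant. That of CRISPR1 in the mutant was 0.415, so none of these lists passed there. Among 10000 random lists matched on level with nitrogen, 0 had a median as low as CRISPR2 or CRISPR3 in either strain. Their middle medians were -0.284 and -0.286 in WT and -0.196 and -0.208 in the mutant. This argues against signal level alone as the source of the CRISPR2 and CRISPR3 medians. Members were drawn independently, whereas probes of CRISPR2 and of CRISPR3 were correlated (estimated 0.441 and 0.328), so 0 of 10000 is no p-value. Fewer copies of the plasmid that carries all 3 arrays would lower CRISPR1 alike, and its lowest median over both strains and 6 scalings was -0.086. The scaling remains open as a source of part of the size: over 6 scalings the CRISPR2 or CRISPR3 median nearest to 0 was -0.849, in the mutant without scaling. In the authors' deposited values the mutant medians were -0.424 and -0.562. Those values also follow the signal before local background subtraction, so their smaller size cannot be put down to scaling alone. Nitrogen supply as a biological explanation was not tested apart from the side of the slide, which it shares, and also stays open.

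On every WT array and no mutant array, 278 probes were well above background, against 2 the other way round. Tested spots adjacent to them had a median mutant minus WT difference of -0.06 (log2), which argues against a defect reaching most of their neighbours. Adjacent spots that were among the 278 were left out and the median is pooled over 1748 spots. It therefore cannot decide on a defect around some of the probes. For lower sensitivity of the mutant arrays, the first test left the whole set open (19.4% above the median WT level of probes measured on all arrays), but it is argued against for 163 probes whose WT level lay over 1 (log2) above the mutant detection limits, since 97.2% of 15972 probes of like WT level, the 163 included, were well above background on all 4 mutant arrays. It stays open for the other 115, where that share was 79.3% of 3777 probes. A sequence missing from the mutant strain also stays open. It was tested on 77 brighter probes with a fitted difference of at least 8-fold lower in both media, chosen whether or not they were among the 278. Of these, 63.6% were well above background on no mutant array, a share between the limits set beforehand for and against a missing sequence. The rest were well above background on some mutant array. A transcript that is shut off would look like a missing sequence, and strain cannot be told apart from the slide row.

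Of 142 CRISPR probes 98 were detected on every WT array, and of these only CRISPR1-23 was detected on no mutant array. Over the whole microarray 278 of 61015 probes had that pattern, so 1 such probe does not set the CRISPR probes apart. A lower level of the whole CRISPR1 array is argued against by the other 46 probes, whose lower median of both media was -0.476. A local defect reaching its neighbours is argued against by a median of -0.118 at 5 adjacent tested spots, from which spots lost themselves were left out. A spacer missing from the CRISPR1 array of the mutant stays open, untested: that the probe was well above background on 0 of 4 mutant arrays only restates the pattern. A changed sequence under the probe would look alike. A fault of 1 spot is argued against, since each array has its own spot of the probe. Levels were -4.44 to -5.16 on the 4 mutant arrays and 0.27 to 0.89 on the 4 WT arrays, and 0 of these spots were flagged. Strain still shares the slide row.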

How the results depend on the processing

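The correlation of the nitrogen responses stayed between 0.548 and 0.69 over 24 alternatives, and lay between 0.41 and 0.735 over 16 choices of 1 array per group. The medians of CRISPR2 and CRISPR3 without nitrogen kept their direction, with CRISPR2 between -2.37 and -1.09 in WT and -1.58 and -0.424 in the mutant, and CRISPR3 between -1.816 and -0.788 and between -1.989 and -0.562; their calls held in 26 of 27 alternatives and ended with an estimated correlation. CRISPR1-23 stayed lower in the mutant in 24 of 24 alternatives in each medium. Over named probes and lists, 1543 values kept direction and side of the threshold, 186 lost the call, 42 gained it, 49 changed sign without a call and 12 reversed. A reversed value changed sign and had a call in the main setting, the alternative or both, so it need not be an opposite call. Signal over background limits the comparisons, since only 27371 of 41714 probes were well above background on all arrays. The cause of the changes below was not tested, except where fewer probes, fewer arrays or a stricter threshold enter by construction.

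Counts are given in the order nitrogen removal in WT and in mutant, mutant minus WT with N and without N, and difference of responses, where they moved over 1.5 times from 14219, 12022, 4781, 1154 and 17. The last 2 were 2491 and 2282 with quantile, 2490 and 1195 with cyclic loess, 759 and 11 with the 75th percentile over probes detected on all arrays, 6695 and 13489 with the authors' deposited values, 2750 and 3755 with probes well above background on all 8 arrays, and 2779 and 2391 with trend and robust. The last was 57 with the median of entering probes and 44 with a common floor. Without scaling they were 1042, 4703, 916, 231 and 0 (3184 at an unadjusted p under 0.05 by limma). Normexp with the 75th percentile gave 21470 for WT and 8153, 4211 and 4929 for the last 3, normexp with quantile 8001, 3597 and 4555, the deposited values at the 75th percentile 8033, 4922 and 5948, and no filter 2872, 739 and 0 (11412 unadjusted by limma). Array weights gave 7198 in WT, 1159 with N and 7523 without N, and only the 4 arrays of a comparison 4634, 499 and 6111. A fitted change of at least 2-fold left 7048, 6329 and 2726 in the first 3, and an adjusted p under 0.01 left 4694, 5040, 1131, 305 and 0 (9278 unadjusted by limma). Leaving out 1 array, with a lone array taken to vary like the other groups, gave 2970 to 19235, 3729 to 18394, 870 to 12027, 208 to 4157 and 0 to 4867.

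Same-numbered replicates deviated from their group means with correlations of 0.0923, -0.108, -0.211, 0.165, 0.222 and -0.207, so the numbers as given show no common pairing. The negative values are those of mutant with N against each other group, and all would be positive with its numbers swapped. Structure shared by the replicates is therefore not excluded. The crossed replicate block uses these swapped numbers and was chosen after the data were seen. With a replicate block the counts were 12296, 10573, 3304, 801 and 0 (8403 unadjusted by limma), and with a crossed replicate block 15748, 12910, 5181, 1470 and 0 (10609 unadjusted by limma).

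Of the reversed values, the CRISPR1 median in WT was 0.08 with the deposited values, 0.137 with these at the 75th percentile and 0.256 without WT with N replicate 2, against -0.387 without WT with N replicate 1. CRISPR3-1 in the mutant was 0.758 with quantile, 0.683 with cyclic loess, 0.609 with the deposited values, 0.364 with these at the 75th percentile and 0.724 with normexp and quantile. With the deposited values LEADER1-4 in the mutant was 0.371, and mutant minus WT without N was 0.137 for CRISPR2-19, 0.111 for CRISPR3-27 and 0.054 for the CRISPR3 list. CRISPR2-19 and CRISPR3-27 had no call there (limma adjusted p = 0.477 and 0.57). The CRISPR3 median still lay below that of all tested probes in those values, which was 0.182 (camera adjusted p = 6.52e-05). The median of all tested probes, in the same order of comparisons, was -0.051, -0.031, -0.057, -0.035 and 0.037. It lay over 0.1 from 0 with the 75th percentile over detected probes (0.122 in the mutant, then -0.221, -0.114 and 0.122), without scaling (0.203, 0.591, -0.273, 0.118 and 0.405) and in the deposited values (-0.113, 0.221, -0.145, 0.182 and 0.333). It also did with normexp at the 75th percentile (-0.108 in WT), no filter (-0.328, -0.222, -0.219 and, for the last, 0.193), probes well above background on all 8 arrays (-0.16 and -0.131 for the first 2) and without WT with N replicate 2 (-0.145 in WT, -0.112 with N and 0.107 for the last).

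Not run were normexp on the mean signal, a slide block (1 slide), other rules for several probes of a gene, protein-coding genes alone, the fixed gene lists and the targeted gene, since the values, names or batches they need are not used here.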
